A study of Mus musculus with 25 samples.

How the data were processed

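RNA was measured in 21 libraries and open chromatin, by ATAC-seq, in 4 pooled samples of mouse skin keratinocytes sorted by flow cytometry. Per the labels' protocols, the RNA libraries were TruSeq preparations of total RNA from sorted cells, sequenced as single reads of 51 cycles, and the ATAC libraries were read from both ends. Per the submitters' processing notes, STAR, Bowtie, Picard and MACS2 2.1.1.20160309 were used with the mouse build mm10. Which tool served which assay beyond the peak caller, the gene counter, its strand setting and the annotation were not given in the sources used here.

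The RNA values deposited by the authors were whole-number counts of reads per gene, with no normalisation. The main table held 24061 gene symbols and 21 library columns. All 21 columns were matched to samples by name and 0 columns were left unmatched, and a line of totals, which equalled the column sums in all 21 libraries, was kept out of every computation. The table held no mitochondrial genes, and 14 symbols had been turned into dates by a spreadsheet. A further count table per library, with Ensembl gene IDs, was deposited for the 8 libraries of the set called CL below. Of its 47729 IDs, 98.9% were matched to a symbol, and it served only as an alternative.

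For ATAC-seq, the authors called peaks with MACS2, per the file headers, from paired ends, keeping duplicate reads, without a control sample and at a q-value of 0.05. Each peak carried the pileup signal at its summit, a fold enrichment (a ratio to the local background), and a -log10 p-value and -log10 q-value, all deposited as the peak caller wrote them, so a score or fold of a peak is the authors' own. The alignment name in the file headers says that samples were pooled, so each population had 1 peak list and no replicates. Whether reads were shifted for the offset of the Tn5 transposase was not given in the sources used here.

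Groups were taken from the sample titles. The set CL held 4 groups of 2 libraries, the set BK 5 libraries and the set DS 8 libraries, of which 6 came from tumours. Nothing in the labels says that libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The counts of libraries in 1 group differed by more than sampling noise (chi-square per degree of freedom 15.7 to 295.5 in the 6 groups with 2 libraries), so no library was counted as a copy of another. The designs, gene lists, rule for named genes and most alternative settings were fixed before the data were examined. Some genes that the rule names are not reported here.

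Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene in the text comes from that test unless another tool is named. The 8 CL libraries were fitted together with 1 mean per group, as were the 5 BK libraries, and the 6 tumour libraries were fitted with genotype as a block. A log2 fold change is given with its standard error, the fold change divided by the square root of its F value. Levels are CPM after TMM scaling, and a group level is the mean of its libraries in the fit that the sentence is about. In the comparisons of levels across sets, all 21 libraries were scaled together.

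A fold against a group in which every library was at 0 was computed against a floor of 3 counts per library and is written as a lower bound. The levels and floors behind these bounds were scaled over all 21 libraries together. Such floors, and the 95% Wilson intervals of the peak shares, cover counting error only. The test was tried on simulated counts with 200 changed genes and a known fold. For HFSC against EpdSC in CL, 84.0% of 4-fold changes were recovered among 14430 genes, with 5.1% false calls, and 0% of 2-fold changes among 14405. The shares for 4-fold changes were 85.0% and 80.0% in the wound responses of the HFSC lineage and EpdSC (14389 and 14396 genes), 83.5% between the wounded groups (14398) and 39.0% for the difference of the responses (14418). They were 62.0% and 24.0% in the BK comparisons (14329 and 14303 genes), with 9.5% and 15.8% false calls. No 2-fold change was recovered in these comparisons. Between the tumour gates 95.5% of 4-fold changes were recovered among 14877 genes, with 13.6% false calls, and 6.5% of 2-fold changes among 14878. A trend with gene length added to the simulated contrast of wounded EpdSC against EpdSC raised the false calls to 29.5%, and removing it brought them to 5.4%.

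Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with at least 3 measured genes, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of each comparison. The 26 lists were HFSC identity, EpdSC identity, basal epithelium, epidermal differentiation, wound keratins and alarm proteins, AP-1, a list of ETS, STAT and NF-kB factors, migration and matrix remodelling, EGF family ligands, cell cycle, cytokines and chemokines, interferon response, glycolysis and hypoxia, TGF-beta targets, EMT, a list of BMP and Wnt signalling, dissociation stress, and markers of immune cells, fibroblasts, endothelial cells, melanocytes, skeletal muscle, adipocytes, erythrocytes, sebaceous gland, and hair matrix and shaft. The genes named in the text were, per tested comparison, the 6 with the largest fold change in each direction among those with an adjusted p under 0.05, groups that did not overlap in CPM and a mean of at least 10 CPM in the higher group, leaving out predicted, ribosomal protein, mitochondrial and pseudogene symbols. Date-like symbols were left out too, which the rule had not foreseen. Up to 4 members per list with the smallest adjusted p were added, every member of the identity lists, and Tgfbr1, Tgfbr2, Hras, Ly6a, Cd34, Itga6 and Itgb1. Members shown because they go against their list, or to give a level beside a rule gene, were chosen after their values were seen. Calls for families of near-identical genes (Sprr, Stfa, the BC117090 and BC100530 genes) are uncertain, since reads could be split between copies.

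Comparisons with 1 library per group were described by log2 ratios of CPM with a prior count of 2, without a p. A gene was counted there when it reached at least 20 CPM and differed by over 2-fold the same way in both gates. For each list the log2 level of a gene against its mean over the DS libraries was taken, and the list median was used. That median was placed among 10000 random lists of the same size matched on mean expression, as a description of those libraries. Genes called between HFSC and EpdSC in BK with a fold over 2 were followed in CL, which shares no library with BK.

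Peak lists were compared with bedtools 2.31.1, counting an overlap of at least 1 bp on the named chromosomes, and the chance level was the mean of 100 circular shifts within chromosomes. Peaks at a gene were counted within its span and 20 kb on either side. Gene positions came from a RefSeq table of assembly GRCm38.p6, the assembly that mm10 names. Gene length here means the genomic span in that table, and 94.7% of the genes with at least 5 CPM in CL had one. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures.

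Alternatives were DESeq2 1.42.0 size factors, no filter on low counts, the DESeq2 Wald test, the replicate letter or number as a block, fits on only the libraries compared, leaving out each library, no genotype block, other thresholds for the BK genes and, for peaks, a -log10 q of at least 5, equal numbers of top peaks and a reciprocal overlap of 50%. Further alternatives were chosen after seeing the data. These were the Ensembl count tables, leaving out both wounded EpdSC libraries, removing a trend with gene length, keeping only genes with a mean of at least 5 CPM in the unwounded stem cell libraries of the other sets, leaving out of the BK genes the markers of other cell types or the genes over 2-fold lower in integrin alpha 6 high than low tumour cells, and size factors for the tumour genotypes. Motif searches were not run.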

Results

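The data came from the epithelial stem cells of mouse skin, in unwounded skin, after wounding and in squamous cell carcinoma (SCC). Hair follicle stem cells (HFSC) reside in the bulge of the follicle and epidermal stem cells (EpdSC) in the layer between follicles, and both can supply cells for wound repair. The libraries allow the question of which genes set the lineages apart, which change on wounding, and which are seen in tumour cells. RNA was counted in 21 libraries. The set CL held 2 libraries each of HFSC, EpdSC, wounded HFSC lineage and wounded EpdSC. HFSC were sorted as CD34 positive and Sca1 negative and EpdSC as CD34 negative and Sca1 positive, both with high integrin alpha 6. Cells of the wounds were sorted by a YFP mark that Sox9CreER had placed, with YFP positive cells as the HFSC lineage and YFP negative cells as EpdSC, so gate and wound changed together. The set BK held 2 libraries of HFSC, 2 of EpdSC and 1 of wounded EpdSC, which was sorted on integrin alpha 6 without the YFP mark. A wound biopsy is also mentioned in the labels of the unwounded samples of BK and CL, which were taken as unwounded by their titles and cell types. The set DS held 6 libraries of grafted tumour cells, with 1 of high and 1 of low integrin alpha 6 for each of the genotypes HRas, HRas TbrKO and TbrKO, and 1 library each of HFSC and EpdSC labelled Tbr. RNA of stem cells came from mice of postnatal day 60.

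Library depth was 28464271 and 22962016 counts in HFSC, 24057702 and 15009407 in EpdSC, 32663874 and 29380965 in the wounded HFSC lineage and 25933047 and 26210837 in wounded EpdSC of CL. In BK it was 32725670 and 33208000 in HFSC, 36425082 and 20833498 in EpdSC and 22281499 in wounded EpdSC. The tumour libraries of high and low integrin alpha 6 had 27888423 and 27146406 for HRas, 27663373 and 22870131 for HRas TbrKO and 26427770 and 28562524 for TbrKO, and the Tbr HFSC and EpdSC libraries had 14216472 and 24113054. The 10 most abundant genes took 6.01% to 14.92% of the counts in 19 libraries, and 20.4% and 17.1% in the wounded EpdSC libraries of CL.

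Genes of follicle stem cell identity were higher in HFSC than in EpdSC of CL. Of 20 measured HFSC identity genes, 16 were higher and 0 lower in HFSC (17 and 0 adjusted over the list alone, a count given below wherever it differs), with a median log2 fold change of 3.35. They included Cd34, the surface marker of the bulge, at 539 against 6.55 CPM (log2 fold change 6.38 ± 0.56, n = 2 libraries per group, edgeR adjusted p = 0.000554). The transcription factors Lhx2 (6.53, 174 against 1.91 CPM), Sox9 (2.84, 157 against 22.0 CPM), Nfatc1 (2.33), Tbx1 (6.16) and Foxc1 (3.86) were higher, as were the Wnt receptor Lgr5 (6.85) and the keratin Krt24 (4.25). The list call held with an estimated correlation (camera adjusted p = 0.0391, and 2.32e-38 at the preset correlation), which no other list did in this comparison. Krt15 (-0.21, edgeR adjusted p = 0.721), Nfib (0.88), Tcf7l2 (0.74) and Npnt (0.66) did not pass. Because the sort used CD34 and Sca1, which Ly6a encodes, the differences in Cd34 and Ly6a (-2.12 ± 0.30, edgeR adjusted p = 0.0037) were partly set by the gate.

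EpdSC identity genes moved both ways, with 3 of 15 higher and 5 lower in HFSC (3 and 6 adjusted over the list alone). Ly6a, Klf5 (-1.61, edgeR adjusted p = 0.0200), Gata3 (-1.60), Thbs1 (-1.97) and the Notch target Hes1 (-1.55) were lower, while the transcription factors Dlx3 (2.41), Sox7 (1.90) and Irx4 (2.89) were higher in HFSC although they stood on the EpdSC list. Ligands and targets of BMP and Wnt signalling were split, with 5 of 11 higher and 2 lower (6 and 3 adjusted over the list alone). Id2 (3.33 ± 0.26) and the Wnt antagonist Nkd1 (6.24) were higher, and Bmp4 fell by 4.06 on the log2 scale, from 62.5 CPM in EpdSC to 3.76 CPM in HFSC. Of 10 TGF-beta targets 3 were higher (4 adjusted over the list alone), among them Ctgf (5.07 ± 0.43, 731 against 21.8 CPM) and Ltbp2 (5.13). The list had a median of -0.06 but a mean of 1.03 and a test direction of up (adjusted p = 0.575 with an estimated correlation). Genes far higher in HFSC included the hedgehog-binding protein Hhip (at least 70.7-fold, 10.8 CPM, at 0 in both EpdSC libraries), the Wnt inhibitor Wif1 (9.89 ± 0.69), which is on the HFSC list, the receptor Gfra2 (9.14), Aspn (7.72), the protease Mme (7.36 ± 0.49) and Crispld1 (7.22). EpdSC exceeded HFSC most in the cadherin Cdh4 (-5.32 ± 0.42), Bmp3 (-5.06), the laminin Lama1 (-4.91), Crispld2 (-4.87), Adamts14 (-4.85) and the decoy receptor Il1r2 (-4.68).

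Epithelial differentiation genes were mixed between HFSC and EpdSC, with 5 of 14 higher and 3 lower (5 and 5 adjusted over the list alone). Calml3 (5.70 ± 0.29) was higher and the suprabasal keratin Krt1 (-2.14, 703 against 3100 CPM) and the transglutaminase Tgm3 (-3.28) lower in HFSC. Among 15 wound keratins and alarm proteins 3 were higher and 1 lower (4 and 2), with Krt6a at 107 against 4.05 CPM (4.73 ± 0.30) and Krt17 at 2300 against 357 CPM, but Krt16 at 22.4 against 98.1 CPM. The list median was 1.17 on fitted values and 0 with genes at 0 in a group set to their bound. Cytokine genes included the alarmin Il33 at 71.3 against 320 CPM (-2.16, edgeR adjusted p = 0.0343), with 1 of 14 higher and 4 lower. Of 12 ETS, STAT and NF-kB factors, Etv4 was higher (3.01) and Ets1 lower (-2.21), with 1 and 2 adjusted over the list alone. No basal epithelium gene of 13 passed with edgeR, although 4 had an unadjusted p under 0.05 and DESeq2 called 0 higher and 2 lower. Krt14 had a log2 fold change of -1.05 (edgeR adjusted p = 0.160) and Itga6 of -1.23 (edgeR adjusted p = 0.173). Markers of dermal fibroblasts were higher in HFSC, with 3 of 8, including Col1a2 (5.36 ± 0.46, 30.2 against 0.753 CPM) and Sparc (1.84). Of 6 sebaceous gland genes 3 were higher and 1 lower (5 and 1), Mgst1 among the higher (2.89), and of 5 melanocyte genes 2 were higher (3), including Dct (3.31). The hair matrix gene Hoxc13 was higher (5.27), alone among 6 in its list.

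In all, edgeR called 1605 of 14831 genes between HFSC and EpdSC of CL, 1067 higher and 538 lower in HFSC. The count rested on single libraries, with 864 genes without HFSC A, 505 without EpdSC A and 645 without EpdSC B, and it was 2502 in a fit of only these 4 libraries.

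BK gave the same comparison in other libraries. HFSC identity genes were again higher in HFSC, 18 of 20 (20 adjusted over the list alone) and 0 lower, with a median of 4.79 (adjusted p = 0.276 with an estimated correlation). Cd34 was at 2800 against 12.0 CPM (7.88 ± 0.68, n = 2 libraries per group, edgeR adjusted p = 0.00321), Sox9 at 248 against 18.3 CPM (3.76 ± 0.35) and Lhx2 at 422 against 5.31 CPM (6.32 ± 0.61). Krt24 (6.84) and Lgr5 (6.58) were higher too, and so was Krt15 (1.46, edgeR adjusted p = 0.0276), while Nfib (1.77) and Tcf7l2 (1.10) did not pass. Klf5 (-3.12 ± 0.41) and Ly6a (-4.45 ± 0.69) were lower in HFSC, with 4 of 15 EpdSC identity genes lower (6 adjusted over the list alone) and 3, namely Dlx3, Irx4 and Tfap2b, higher. Proliferation genes were lower in HFSC, 18 of 20 cell cycle genes (20 adjusted over the list alone), among them the cell division markers Mki67 (-4.07, 22.2 against 373 CPM), Birc5 (-3.12), Ube2c (-3.39) and Ccna2 (-3.20), with adjusted p = 0.276 with an estimated correlation. In CL, by contrast, 1 of 20 cell cycle genes passed (0 adjusted over the list alone), Rrm2 (0.84), and the difference between the sets was not tested.

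Signalling genes of several lists were lower in HFSC than in EpdSC of BK, although no list call of this comparison held with an estimated correlation (adjusted p = 0.276 for the AP-1, dissociation stress, cytokine and ETS, STAT and NF-kB lists and 0.284 for the EGF family). Of 9 AP-1 genes 6 were lower (8 adjusted over the list alone), including the immediate early genes Fos (-2.39), Atf3 (-3.30 ± 0.36) and Junb (-2.47). Of 12 dissociation stress genes 9 were lower (1 higher and 9 lower adjusted over the list alone), including Zfp36 (-2.84). Of 6 growth factors of the EGF family Epgn (-4.86 ± 0.56, 6.09 against 177 CPM), Hbegf (-3.35) and Tgfa (-1.85) were lower (1 higher and 4 lower adjusted over the list alone). The cytokine Il33 (-4.04 ± 0.45) and its relative Il1rn (-2.96) were lower as well, with 7 of 14 cytokine genes (11 adjusted over the list alone), and so were the ETS factors Ehf (-3.19) and Ets1 (-2.73). Higher in HFSC were Ctgf (7.41 ± 0.44, 2220 against 13.1 CPM), Ltbp2 (7.15), Id2 (4.79) and Sfrp1 (3.87), and Bmp4 was lower (-4.19). Fibroblast markers were higher again, 4 of 7, with Col1a2 at 63.8 against 0.620 CPM, and Dct was at 29.2 against 0.799 CPM. Large differences, in no order where a group was at 0, included Scrg1 (at least 142-fold), Sphkap (at least 126-fold), the hair keratin-associated gene Krtap17-1 (at least 89.9-fold), Slc22a22 (at least 89.4-fold), Scarf2 (8.36) and Wfdc3 (8.20), and on the other side Bmp3 (-5.46), Ppp2r2c (-5.03), Svopl (-4.99), Adamts14 (-4.89) and Il20ra (-4.84).

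EdgeR called 2108 of 14663 genes in BK, 1160 higher and 948 lower in HFSC. The count was 1260 without HFSC 1, 1378 without HFSC 2, 6486 without EpdSC 1, with 48.6% higher against 55.0%, and 4903 without EpdSC 2. Of the genes higher in BK, 650 were also called higher in CL, against 83 for independent lists, 293 were called lower in both, against 36, and 15 went opposite ways. Of 2061 BK genes 87.7% had the same sign in CL, and the log2 fold changes had r = 0.702 across genes, which are not independent replicates.

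**Figure D1:**
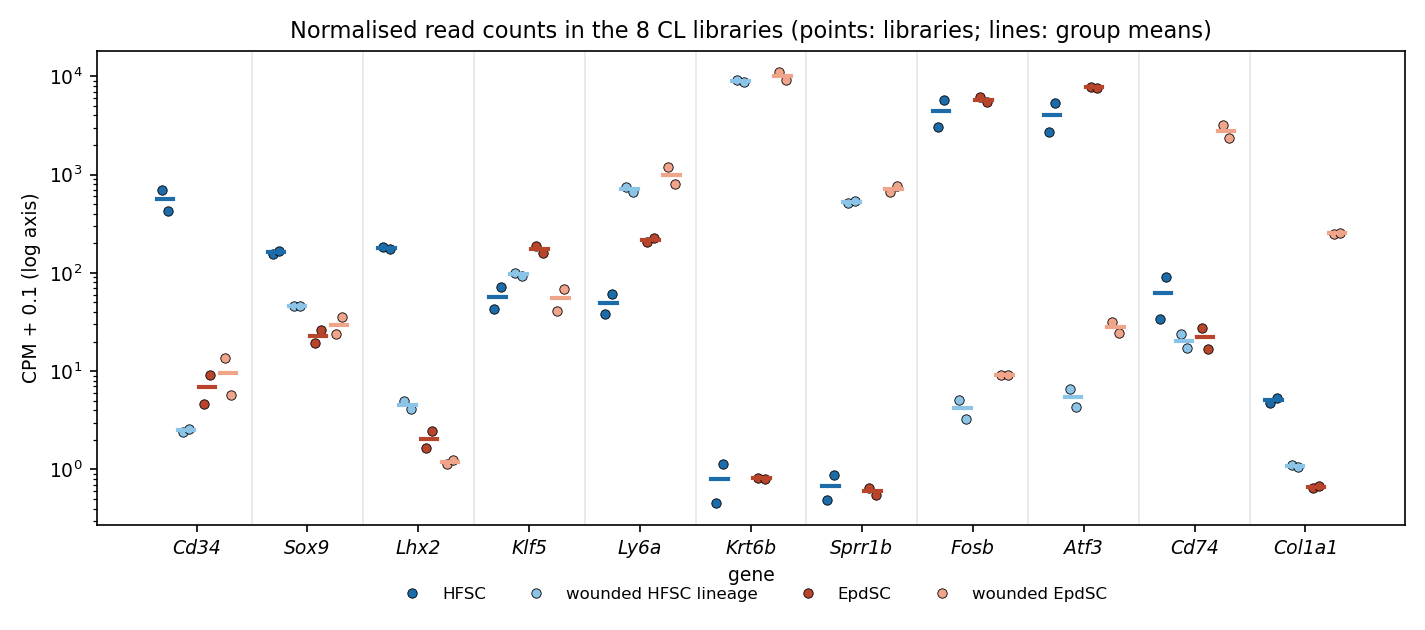
Levels of 11 genes in the 8 CL libraries, in CPM plus 0.1 on a log axis, with points for libraries and lines for group means. Cd34 stood at 539 CPM in HFSC and 2.30 CPM in the wounded HFSC lineage, Krt6b rose from 0.677 to 8630 CPM, and Cd74 and Col1a1 stood highest in wounded EpdSC (2650 and 243 CPM).

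After wounding, the HFSC lineage lost follicle stem cell transcripts and gained wound keratins. All but 1 of 20 HFSC identity genes fell (19 lower and 0 higher), with a median of -3.26 (adjusted p = 0.0658 with an estimated correlation, 6.69e-16 at the preset correlation). Cd34 fell from 539 to 2.30 CPM (-7.87 ± 0.61, n = 2 libraries per group, edgeR adjusted p = 8.1e-05), Lhx2 from 174 to 4.23 CPM (-5.36 ± 0.26). Krt15 fell from 9940 to 264 CPM (-5.23 ± 0.29) and Lgr5 from 115 to 3.70 CPM (-4.95). Sox9 fell less, from 157 to 44.2 CPM (-1.83 ± 0.26, edgeR adjusted p = 0.00113), and Runx1 did not pass (-0.23). The sort differed between the groups, as the unwounded HFSC were gated on CD34 and the wounded cells on YFP.

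Wound keratins and alarm proteins rose in the HFSC lineage, 13 of 15 (14 adjusted over the list alone), with a median of 8.71 and a call that held with an estimated correlation (camera adjusted p = 0.0126), which no other list did in this comparison. Krt6b rose from 0.677 to 8630 CPM (13.68 ± 0.58), Krt6a from 107 to 12900 CPM (6.91 ± 0.33), the cornified envelope gene Sprr1b from 0.559 to 506 CPM (9.85 ± 0.38) and the alarmin S100a8 from 0.541 to 208 CPM (8.57 ± 0.57). Ly6a rose from 47.8 to 682 CPM (3.83 ± 0.32), whereas Klf5 had a log2 fold change of 0.75 that did not pass (edgeR adjusted p = 0.0987). Of 15 EpdSC identity genes 4 rose (5 adjusted over the list alone), with the barrier regulators Grhl3 (1.60), Ovol1 (2.09) and Grhl1 (0.89) beside Ly6a, and 8 fell (9), including Klf4 (-2.43), Tfap2b (-2.67) and Notch1 (-1.90). Differentiation genes rose, 10 of 14 with 1 lower, including Krt1 (4.85 ± 0.47), Krt10 (2.84) and Tgm1 (3.75), with adjusted p = 0.0658 with an estimated correlation. Basal epithelium genes went both ways, 2 of 13 higher, Krt14 (2.66 ± 0.42) among them, and 4 lower, including Dst (-2.58) and Itgb4 (-1.46), and the list had a median of -0.14 and a mean of 0.07.

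Immediate early genes fell steeply. Of 10 AP-1 genes 9 fell, with a median of -4.30 (adjusted p = 0.217 with an estimated correlation), including Fosb from 4270 to 3.91 CPM (-10.09 ± 0.50), Atf3 from 3890 to 5.07 CPM (-9.58 ± 0.51), Fos from 6730 to 48.8 CPM (-7.11 ± 0.55) and Jun (-4.85). Of 12 genes that dissociation is known to induce, 11 fell, among them Egr1 (-6.93 ± 0.31) and Zfp36 (-6.59), with adjusted p = 0.0658 with an estimated correlation. Genes of BMP and Wnt signalling fell, 10 of 11 (1 higher and 10 lower adjusted over the list alone), with Id2 (-4.58 ± 0.28), Id3 (-4.13), Bmp2 (-2.94) and Axin2 (-2.02) among them (adjusted p = 0.0686 with an estimated correlation). TGF-beta targets were split, 4 higher and 4 lower of 10, with Pmepa1 (4.93) up and Ltbp2 (-8.95) and Ctgf (-5.86) down, so that the median was 0.13, the mean -0.51 and the test direction down. Of ETS, STAT and NF-kB factors 5 of 12 rose and 3 fell (5 and 4 adjusted over the list alone), Elk3 (3.85), Ets1 (2.16) and Ehf (1.52) among those that rose and Relb (-1.87) among those that fell.

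Glycolysis and hypoxia genes rose, 11 of 12 with a median of 2.05 (adjusted p = 0.0658 with an estimated correlation), including the glucose transporter Slc2a1 (2.87 ± 0.26), Ldha (2.69 ± 0.23), Pgk1 (2.99) and Bnip3 (2.73). Migration and matrix remodelling genes rose, 11 of 16 with 1 lower, including the collagenase Mmp13 (10.48 ± 0.69), the actin bundler Fscn1 (6.28 ± 0.47), Mmp9 (7.16) and Plau (2.97), with adjusted p = 0.294 with an estimated correlation. The cytokines Tslp (5.20 ± 0.29), Il24 (5.78) and Il33 (2.72) rose and Ccl2 (-3.21) and Cxcl10 (-2.41) fell, with 5 of 14 higher and 4 lower (8 and 4 adjusted over the list alone). Of 20 cell cycle genes 9 rose, including Ccnb2 (1.62) and Birc5 (1.52) (adjusted p = 0.253 with an estimated correlation), and of 12 interferon response genes 5 rose. No gene of the EGF family passed with edgeR, where 2 of 6 had an unadjusted p under 0.05 and DESeq2 called 3 higher. Of 9 EMT genes Fn1 fell (-3.54) and the others did not pass. Immune cell markers were 1 higher and 4 lower of 9, the higher being Lyz2 at 2.59 against 0.103 CPM and the lower including the Langerhans cell gene Cd207 (-3.75) and Cd74 (-1.64). Of 8 fibroblast markers 2 rose and 2 fell, Col1a2 (-4.19) among the latter. The adipocyte gene Fabp4 (14.0 against 0.0564 CPM) and the muscle gene Mylpf were higher, each the measured gene of its list.

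Strongly raised genes, in no order where a group was at 0, included BC117090 (at least 5840-fold), the protease Tmprss11g (at least 1230-fold), Sprr2d (at least 614-fold), Stfa2 (at least 565-fold), BC100530 (12.88 ± 0.47) and Krt6b. Myoc (at least 1320-fold lower), Chat (at least 630-fold), Cck (at least 234-fold), Grik1 (at least 223-fold), Fam71a (at least 134-fold) and Lrrn1 (at least 133-fold) were at 0 in the wounded HFSC lineage. EdgeR called 6835 of 14831 genes, 3167 higher and 3668 lower, and the count was 4064 without wounded HFSC lineage A and 4408 without wounded HFSC lineage B, where 52.4% were higher against 46.3%.

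Wounded EpdSC of CL shared the wound keratins and the loss of immediate early genes. All 15 wound keratins and alarm proteins rose, with a median of 10.03 (9.15 with genes at 0 at their bound) and a call that held with an estimated correlation (camera adjusted p = 0.0258), which no other list did in this comparison. Krt6a rose from 4.05 to 16800 CPM (12.03 ± 0.40, n = 2 libraries per group, edgeR adjusted p = 1.19e-05), Krt6b from 0.689 to 9680 CPM (13.77 ± 0.59), S100a8 from 0.214 to 255 CPM (10.03 ± 0.64) and Sprr1b from 0.482 to 686 CPM (10.44). AP-1 genes fell, 9 of 10 with 1 higher and a median of -4.23 (adjusted p = 0.279 with an estimated correlation), including Fosb (-9.33 ± 0.48), Atf3 (-8.12 ± 0.48) and Fos (-6.84). Of dissociation stress genes 9 of 12 fell and 2 rose, with Egr1 at -6.71 ± 0.30. Differentiation genes rose, 10 of 14 with 1 lower, such as Tgm1 (6.21) and Calml3 (5.39), with adjusted p = 0.115 with an estimated correlation for this and for the dissociation stress list. Basal epithelium genes were 2 higher and 6 lower of 13, with Krt14 at 75000 against 12400 CPM and Trp63, a master regulator of basal keratinocytes, at 356 against 1190 CPM (-1.74, edgeR adjusted p = 0.00175).

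Identity genes of both lineages moved in wounded EpdSC. Of EpdSC identity genes 6 of 15 rose and 7 fell, with Gata3 (-3.41 ± 0.29), Hes1 (-3.23 ± 0.22), Klf4 (-3.73) and Klf5 (-1.67) lower and Ly6a (2.21 ± 0.30), Irx4 (2.08), Ovol1 (1.61) and Grhl3 (1.21) higher. Of HFSC identity genes 5 of 20 rose and 9 fell (6 and 10 adjusted over the list alone), with Krt15 from 11500 to 176 CPM (-6.03 ± 0.30), Npnt (-5.01) and Nfib (-4.40) lower and Dkk3 (1.53) and Tcf7l1 (1.31) higher. Sox9 (0.38, edgeR adjusted p = 0.236) and Cd34 (0.49, edgeR adjusted p = 0.386) did not pass. BMP and Wnt genes were 3 higher and 6 lower of 11 (3 and 7 adjusted over the list alone), with Bmp4 (-6.60 ± 0.50) and Bmp2 (-5.41) lower and Id2 (1.98) higher. Glycolysis genes rose, 10 of 12, including Hk2 (2.99), Ldha (3.25) and Aldoa (2.77), with adjusted p = 0.115 with an estimated correlation, and 14 of 20 cell cycle genes rose, including Rrm2 (2.39) and Birc5 (2.04), with adjusted p = 0.279 with an estimated correlation. Of 12 ETS, STAT and NF-kB factors 3 rose, Elk3 (4.12) and Elf3 (2.74) among them, and 4 fell, with a median of -0.08 and a mean of 0.18. The EGF family was split, Areg (2.20) and Tgfa (1.54) higher and Hbegf (-2.05) and Epgn (-2.76) lower. Of 12 interferon response genes 9 rose and 1 fell (9 and 2 adjusted over the list alone), including Irf7 (2.39) and Oas2 (5.37) (adjusted p = 0.429 with an estimated correlation), and of 10 TGF-beta targets 6 rose and 2 fell, with Cdkn2b (3.22) and Ctgf (-2.52) as examples.

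Wounded EpdSC libraries also held RNA of genes typical of other cell types. All 9 immune cell markers rose (median 6.96, adjusted p = 0.242 with an estimated correlation), with Cd74 from 21.3 to 2650 CPM (6.96 ± 0.59), H2-Aa from 10.4 to 1310 CPM (6.98 ± 0.47) and Tyrobp from 0.687 to 134 CPM (7.57 ± 0.49). All 8 fibroblast markers rose (median 6.24, adjusted p = 0.115 with an estimated correlation), with Col1a1 from 0.545 to 243 CPM (8.79 ± 0.26), and 4 of 5 endothelial markers rose, Pecam1 reaching 8.03 CPM. The same libraries held higher Vim (5.91 ± 0.50), 7 of 9 EMT genes, 6 of 14 cytokine genes (7 adjusted over the list alone, with 3 lower) such as Cxcl2 (8.35) and Il1b (7.32), and 12 of 16 migration genes (13 adjusted over the list alone) with Itga5 (3.81) and Mmp9 (10.14), lists that such cells express too. The adjusted p of the EMT and migration lists was 0.549 and 0.279 with an estimated correlation. Melanocyte markers rose, 4 of 5 with Dct (3.64), as did the lone adipocyte, muscle and erythrocyte genes measured, Fabp4 (8.99), Mylpf and Alas2 (6.06, 28.1 against 0.411 CPM). Sebaceous genes were 2 higher and 1 lower of 6, Mgst1 (4.06) and Scd1 (-2.42) as examples, with a median of -0.10 and a mean of 1.22, and hair matrix genes 1 higher and 1 lower of 6.

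BC117090 (at least 3010-fold), the complement gene C1qb (at least 1000-fold), Mmp13 (at least 855-fold), Cdhr1 (at least 764-fold), Sprr2d (at least 567-fold) and Kcnk1 (at least 472-fold) were strongly raised and at 0 in EpdSC. Egr4 (at least 160-fold lower), Trpm3 (at least 129-fold), Prrg3 (at least 98.8-fold), Gpha2 (-10.60 ± 0.59), the receptor Ntrk2 (-9.87 ± 0.67) and Fosb were strongly reduced, in no order where a group was at 0. EdgeR called 8663 of 14831 genes, 4482 higher and 4181 lower, and 5735 without EpdSC A. The share higher was 51.7%, 47.0% without wounded EpdSC B and 48.6% among genes seen in other unwounded libraries. DESeq2 size factors moved the median log2 fold change of all genes by 0.11, from -0.04 to 0.07. Fold changes in these libraries fell with gene length (Spearman rho -0.369 across genes, against -0.127 in the wounded HFSC lineage), and within the set the deviations of the 2 wounded EpdSC libraries had rho of -0.464 and -0.304. The wound responses shared no library, but wounded libraries of the same letter deviated together (r = 0.455). In both, 2167 genes were called higher, against 957 for independent lists, and 2181 lower, against 1034, with 338 opposite.

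**Figure D2:**
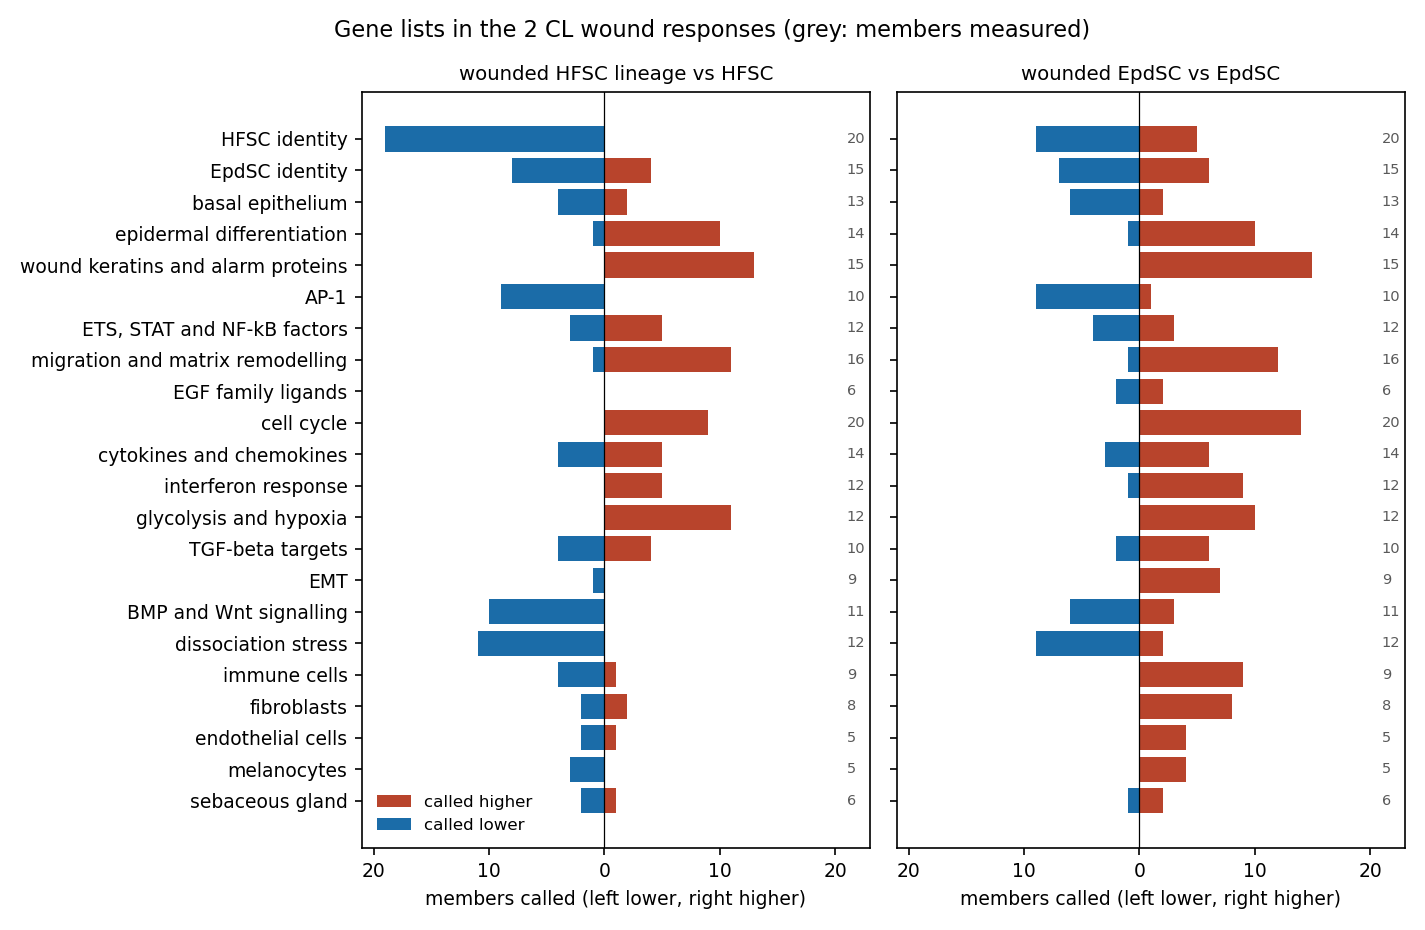
Members of each fixed gene list called higher or lower by edgeR in the wound responses of the HFSC lineage and of EpdSC in CL, with the number of members measured printed in grey. Wound keratins and alarm proteins rose in both (13 and 15 of 15), AP-1 genes fell in both (9 of 10), and immune cell markers rose in EpdSC (9 of 9).

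The wounded groups of CL differed in RNA of leukocytes and fibroblasts, and in some follicle genes. Wounded HFSC lineage cells had less Cd74 (19.4 against 2650 CPM, -7.09 ± 0.59, n = 2 libraries per group, edgeR adjusted p = 0.000588), less H2-Aa (-6.84 ± 0.47) and less Col1a1 (0.936 against 243 CPM, -8.01 ± 0.24) than wounded EpdSC. All 9 immune markers, 6 of 8 fibroblast markers (7 adjusted over the list alone), 2 of 5 endothelial (3) and 3 of 5 melanocyte markers (4) were lower, with adjusted p = 0.151 for the immune and for the fibroblast list with an estimated correlation, and no list call of this comparison held with it. The lower genes of other lists included Vim (-5.70 ± 0.49), Fn1 (-4.05), Il1b (-6.59), Cxcl2 (-6.83), Plaur (-2.71), Irf7 (-1.95) and Tgfb1 (-1.91). Of the lists, 7 of 9 EMT (8 adjusted over the list alone, with 1 higher), 4 of 16 migration, 4 of 12 interferon (6) and 3 of 10 TGF-beta genes were lower. Of HFSC identity genes 8 of 20 were higher and 1 lower (10 and 1 adjusted over the list alone), with Foxc1 (2.78 ± 0.34, 12.6 against 1.82 CPM), Lgr5 (3.03 ± 0.39, 3.70 against 0.453 CPM), Lhx2 (2.01 ± 0.26, 4.23 against 1.05 CPM) and Npnt (2.18 ± 0.25) higher at low levels. Cd34 was lower (-1.99 ± 0.49, 2.30 against 9.16 CPM, edgeR adjusted p = 0.0359). Sox9 (0.63, edgeR adjusted p = 0.0935), Krt15 (0.59, edgeR adjusted p = 0.102), Nfatc1 (0.14), Klf5 (0.80), Ly6a (-0.49, 682 against 960 CPM) and Krt6a (-0.38) did not pass. Of 15 EpdSC identity genes 4 were higher in the HFSC lineage, namely Tfap2b (1.50), Grhl1 (0.91), Klf4 (1.21) and Sox7 (0.72), and 0 lower.

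AP-1 and dissociation stress genes were lower in the wounded HFSC lineage than in wounded EpdSC for 4 of 10 (5 adjusted over the list alone) and 5 of 12 (7), including Atf3 (-2.41) and Junb (-1.15), and the BMP target Id2 was lower too (-3.23). Differentiation genes such as Calml3 (1.15) and Dsg1a (1.39) were higher, 3 of 14. Large differences among genes with at least 10 CPM in the higher group were, upward, Cep290 (3.52), the X-inactivation transcript Xist (3.01 ± 0.70, 432 against 53.8 CPM), Igfl3 (2.98), Adamts5 (2.96), Cgnl1 (2.81) and Foxc1, and downward the lymphocyte and dendritic cell genes Cd8a (-9.55), Ltb (-8.74), Ccl22 (-8.59), Nkg7 (-8.49), AI467606 (-8.06) and Col1a1. EdgeR called 2847 genes, 1008 higher and 1839 lower, with a trend of fold change with gene length (Spearman rho 0.441 across genes). The balance depended on the setting. DESeq2 size factors gave 3536 genes and the DESeq2 Wald test 5336, with 46.8% higher against 35.4%. Without the filter on low counts 2178 were higher and 2125 lower, and in a fit of only these 4 libraries 83 and 954. The count was 1524 and 1458 without HFSC A or B, 931 and 935 without EpdSC A or B, 541 without either wounded HFSC lineage library, 900 without wounded EpdSC A and 7460 without wounded EpdSC B, where 4078 were higher and 3382 lower, while the other libraries left out gave 10.5% to 19.9% higher.

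The difference between the wound responses of the lineages was tested as an interaction. Of 20 HFSC identity genes 11 had a lower and 1 a higher response in the HFSC lineage than in EpdSC (13 and 1 adjusted over the list alone), with a median difference of -2.20 (adjusted p = 0.313 with an estimated correlation). Krt6a rose less in the HFSC lineage (difference -5.12 ± 0.39, n = 2 libraries in each of 4 groups, edgeR adjusted p = 0.000416), from its higher start, and Krt17 (-3.42), Calml3 (-4.55), Ltbp2 (-7.28), Id2 (-6.56) and Hk2 (-2.08) had lower responses there too. Bmp4 (4.14) and Trp63 (1.60) had higher ones. Markers of immune cells were lower for 8 of 9 (9 adjusted over the list alone), of fibroblasts for 5 of 8, and EMT genes for 7 of 9 (adjusted p = 0.313, 0.127 and 0.536 with an estimated correlation), with Col1a1 at -11.14 ± 0.32 and Cd74 at -8.60. EdgeR called 2339 genes, 788 with a higher and 1551 with a lower response in the HFSC lineage, and the DESeq2 Wald test 3909, with 42.7% higher against 33.7%. The count was 1412 and 1171 without HFSC A or B, 789 and 992 without EpdSC A or B, 1128 and 1080 without wounded HFSC lineage A or B and 6499 without wounded EpdSC B, where the balance turned to 3688 with a higher and 2811 with a lower response.

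Genes chosen in BK alone were followed into the wounds of CL. There the 1116 measured genes that BK had placed higher in HFSC had a median log2 fold change of 2.32 between HFSC and EpdSC (650 called higher and 0 lower, camera adjusted p = 0.00403 with an estimated correlation). On wounding they fell in the HFSC lineage, with a median of -2.06 (quartiles -3.99 to -0.79), 739 called lower and 52 higher (camera adjusted p = 0.0198 with an estimated correlation). In EpdSC they had a median of 0.33 with 387 higher and 227 lower (0.536). The difference of these responses had a median of -2.48 (camera adjusted p = 0.0107 with an estimated correlation). It contains the unwounded gap for which the genes were chosen, and genes scarce in EpdSC could hardly fall there. It is no separate support. The 945 genes higher in EpdSC of BK had a median of -0.79 in wounded EpdSC, with 456 lower and 197 higher (adjusted p = 0.407 with an estimated correlation), and of 0.10 in the wounded HFSC lineage. Between the wounded groups the sets had medians of -0.13 and 0.08 and neither passed (camera adjusted p = 0.636 and 0.918 with an estimated correlation). The fixed HFSC identity list stood higher there in the HFSC lineage, with a median of 0.99, 8 of 20 genes higher and 1 lower (adjusted p = 6.47e-05 at the preset and 0.388 with an estimated correlation). The HFSC-high set also held genes of other cell types, since 4 of 7 fibroblast markers were higher in HFSC of BK, and the fibroblast list had a median of -5.50 between the wounded groups and of -5.20 for the difference of the responses (adjusted p = 0.151 and 0.127 with an estimated correlation). Without the genes over 2-fold lower in integrin alpha 6 high than low tumour cells, left out after seeing the data, 863 genes remained in the set and its medians were -1.83 in the wounded HFSC lineage, -0.02 between the wounded groups and -2.15 for the difference of the responses (camera adjusted p = 0.0370, 0.929 and 0.0231 with an estimated correlation). The gap between the sets went from 3.01 in unwounded to -0.21 in wounded cells, with an SD of 0.11 over the 4 pairs of wounded libraries. The call for the HFSC lineage was lost without wounded HFSC lineage A (camera adjusted p = 0.0527) or B (0.0540) and without wounded EpdSC A (0.0830) or B (0.0970), all with an estimated correlation and with medians of -2.10 to -2.07.

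**Figure D3:**
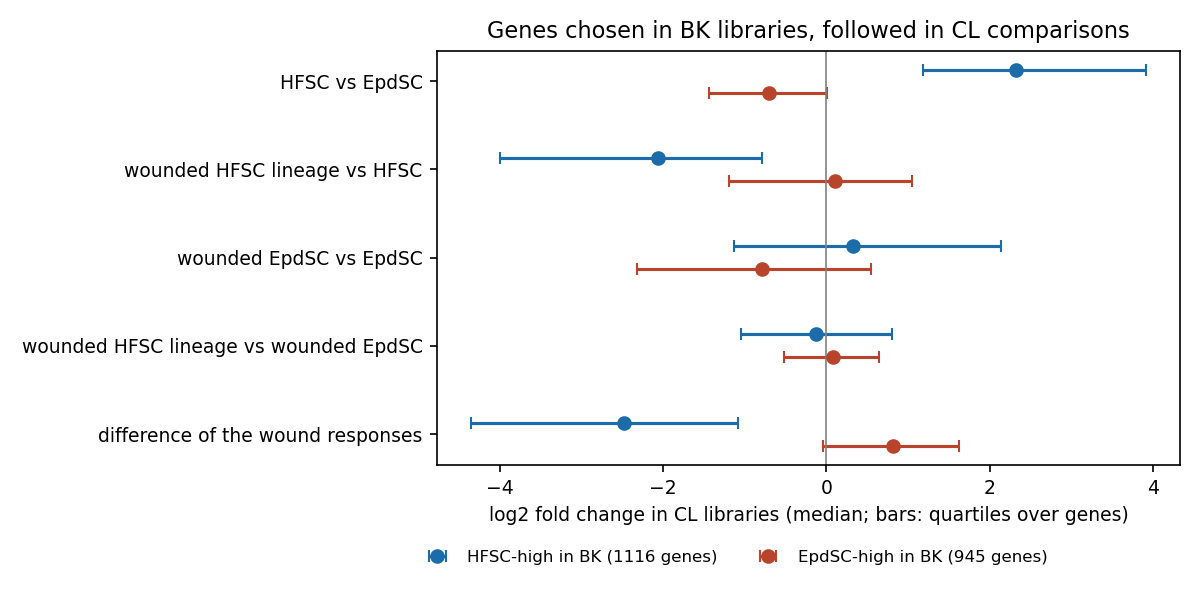
Median log2 fold change, with quartiles over genes as bars, of the 1116 HFSC-high and 945 EpdSC-high genes of BK in the 5 comparisons of CL. The HFSC-high genes stood at 2.32 between unwounded HFSC and EpdSC, at -2.06 after wounding of the HFSC lineage and at -0.13 between the wounded groups.

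In BK, wounded EpdSC were measured in 1 library against 2 of EpdSC, and the lone library was assumed to vary like the other groups. The differences below are those of 1 library, which also differed from its controls in sex-linked RNA, and are not assigned to the wound. Krt15 was lower (-2.66 ± 0.42, 1400 against 8880 CPM, edgeR adjusted p = 0.0445), as were Fos (-2.71), Fosb (-3.18, 501 against 4530 CPM), Notch1 (-2.64) and the hemidesmosome genes Col17a1 (-2.57) and Itgb4 (-2.52). Postn (4.64 ± 0.40, 4320 against 173 CPM), Fst (2.67), the ETS factor Ehf (2.94), Ccl2 (3.03) and Il1b (3.05) were higher. Of 9 AP-1 genes 2 were lower (4 adjusted over the list alone), of 13 basal genes 3 (4), and of 14 cytokines 2 were higher (9 higher and 1 lower adjusted over the list alone). No list call of this comparison held with an estimated correlation (adjusted p = 0.727 for the AP-1 and cytokine lists). None of 15 wound keratins and alarm proteins passed with edgeR (5 higher adjusted over the list alone), where 6 had an unadjusted p under 0.05 and DESeq2 called 8 higher. The list had a median of 2.78 with S100a8 at 4.57 and Krt6a at 1.51. Scaled over all 21 libraries, Krt6a stood at 1610 and 137 CPM in the EpdSC libraries of BK and 2590 CPM in the wounded one. In EpdSC of CL it stood at 3.64 and 4.69 CPM, so its change in BK was against a higher and uneven baseline. Sox9 (0.01), Cd34 (-1.69, edgeR adjusted p = 0.143) and Ly6a (-0.38) did not pass.

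The Y-linked genes Eif2s3y (at least 405-fold lower), Uty (-9.22), Ddx3y (-8.95) and Kdm5d (-8.59) and Xist (9.38 ± 2.05, 2030 against 3.12 CPM) had large differences in the BK wound comparison, so wounded and unwounded libraries differed in sex-linked RNA although all were labelled female. Other large differences among genes with at least 10 CPM in the higher group were C1qtnf1 (-5.10) and Arsi (-4.86) downward, and Krt25 (5.60), Akr1c18 (5.53), Jakmip2 (5.13), Tmprss11g (4.87) and Pyy (4.79) upward. Markers of hair matrix and shaft were higher for 2 of 6, Krt25 and Krt71 (6.26 ± 0.68), with 3 higher and 1 lower adjusted over the list alone and a median of 3.56 (adjusted p = 0.00889 at the preset and 0.727 with an estimated correlation). The adipocyte gene Fabp4 was higher too (7.67 ± 1.11, 4.44 against 0.0146 CPM). EdgeR called 1169 of 14663 genes, 259 higher and 910 lower, with a smallest adjusted p of 0.0445. DESeq2 called 3410, with 37.0% higher against 22.2%, and removing the trend with gene length gave 2401, with 42.8% higher. The count was 6848 without EpdSC 1 and 6635 without EpdSC 2. Of 1160 BK genes 81.5% had the same sign in the CL wound response of EpdSC, with 597 called lower in both against 266 for independent lists, 99 higher in both against 72, and 52 opposite.

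Tumour cells of high integrin alpha 6 were compared with those of low integrin alpha 6, 3 libraries each, with genotype as a block. The low cells held more RNA of stroma, leukocytes and alarm proteins. The high cells had less of the collagen-binding proteoglycan Dcn (73.1 against 446 CPM, -2.63 ± 0.15, n = 3 libraries per group, edgeR adjusted p = 0.0182), fibronectin Fn1 (144 against 766 CPM, -2.44 ± 0.17), the leukocyte antigen Ptprc (-2.31) and S100a8 (125 against 429 CPM, -1.77 ± 0.12). Fibroblast markers were lower for 6 of 8 (8 adjusted over the list alone), including Lum (-2.48), Pdgfra (-2.62), Col1a1 (-2.47 ± 0.40) and Col3a1 (-2.47). Immune markers were lower for 6 of 8 (8 adjusted over the list alone), including Cd74 (-1.52) and Tyrobp (-2.17), with adjusted p = 0.251 for each list with an estimated correlation. EMT genes were lower, 7 of 10 (with 1 higher adjusted over the list alone), with Prrx1 (-2.60), Pdgfrb (-2.79), Snai1 (-2.27) and Vim (-1.26), in the cells that had less fibroblast RNA. No list call between the gates held with an estimated correlation. Wound keratins and alarm proteins were lower for 4 (10 adjusted over the list alone), with S100a9 (-1.88), Sprr2d (-1.60) and Lcn2 (-2.48), the cytokine Il1b was lower (-2.35) and so was the desmosome gene Dsg1a (-2.49).

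Higher in integrin alpha 6 high tumour cells were Itga6 itself (0.94 ± 0.16, 1460 against 788 CPM, edgeR adjusted p = 0.0498), which the gate selected, and 3 of 20 cell cycle genes, Mcm2 (0.73), Mcm3 (0.71) and Cdc20 (0.70). Adjusted over the list alone 20 of 20 cell cycle and 8 of 13 basal epithelium genes were higher, with medians of 0.62 and 0.56 (adjusted p = 0.411 and 0.400 with an estimated correlation). Of the fixed largest genes only Nlrp10 (1.15 ± 0.18), Pi15 (1.11) and Gyltl1b (0.83) met the rule upward, and downward Tspan1 (-3.77 ± 0.40), Cyp4f18 (-3.32), Rab44 (-3.23), Wdfy4 (-3.19), Pik3ap1 (-3.04) and Hp (-3.03) led. No HFSC identity gene of 19 and no AP-1 gene of 10 passed with edgeR, where 3 and 2 had an unadjusted p under 0.05 and DESeq2 called 2 and 1 higher. Sox9 (-0.20), Cd34 (-0.20), Klf5 (0.50, edgeR adjusted p = 0.125) and Ly6a (0.56, edgeR adjusted p = 0.109) did not pass.

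In the tumours edgeR called 476 of 15113 genes, 23 higher and 453 lower in the high cells. DESeq2 size factors gave 256, the DESeq2 Wald test 1692 with 20.4% higher against 4.8%, and without the TbrKO pair the count was 2908. It was 0 with edgeR without the HRas pair or the HRas TbrKO pair, where 1685 and 1684 genes had an unadjusted p under 0.05.

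Tumour genotypes had 1 library per gate and no replicate check, so log2 ratios are given in the high and low gates without a p. TbrKO tumours had almost no RNA of several genes that HRas tumours expressed, including the chromatin protein Hmga2 (0.961 against 543 CPM in the high gate and 2.19 against 421 CPM in the low gate), Gap43 (-9.51 and -8.20), Disp2 (-8.48 and -6.78), Nptx1 (-7.68 and -7.21) and Prl8a9 (-6.34 and -7.12). They held more Tmem178 (7.56 and 5.09), Plb1 (5.69 and 6.54), Clmn (6.56 and 5.60), Col4a6 (6.43 and 5.34), Wfdc18 (5.13 and 6.46) and Bpifa2, which HRas tumours had at 0 and TbrKO tumours at 21.6 and 141 CPM. In both gates 694 genes were over 2-fold higher and 576 lower of 8200. Against HRas TbrKO tumours, 620 were higher, with Clmn (6.85 and 5.99), Mme (7.56 and 5.11) and Alox12 (5.85 and 6.46), and 544 lower of 8150, with Hmga2 at -8.41 and -6.87 beside Scg2, Gap43, Disp2 and Nptx1.

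HRas TbrKO and HRas tumours differed less, with 103 genes higher and 19 lower of 7607. The interferon-induced GTPases Gbp2 (3.13 and 2.81) and Iigp1 (3.15 and 2.41), Irg1 (1.90 and 3.40), Sprr2f (2.50 and 3.13), Klk13 (2.42 and 2.40) and S100a7a (2.34 and 2.39) were higher in HRas TbrKO. Tmem47 (-2.55 and -1.60), Samd5 (-1.67 and -1.68), Ctla2b (-1.40 and -1.91), Nuak1 (-2.19 and -1.01), the simple epithelial keratin Krt8 (-1.46 and -1.58) and Timp1 (-1.64 and -1.40) were lower. The labels do not say what Tbr stands for, and the TGF-beta receptor genes were fixed for reporting. Tgfbr2 was at 213 and 228 CPM in HRas TbrKO, 198 and 224 CPM in HRas and 455 and 187 CPM in TbrKO tumours, and Tgfbr1 ranged from 64.0 to 97.7 CPM over the 8 DS libraries, but whole-gene counts check nothing about a deleted exon. Hras stood at 253 and 217 CPM in HRas tumours and at 138 and 154 CPM in TbrKO tumours.

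The Tbr-labelled HFSC and EpdSC of DS were compared in 1 library each. Of 2103 genes that BK had called and that had reads, 99.0% had the same sign, a description of this pair of libraries without an error estimate. Tbr HFSC had Cd34 at 1070 against 3.55 CPM (8.21), and higher Wfdc3 (9.29), Angptl7 (8.71), Chat (8.70), Il31ra (8.32) and Col8a2 (8.15), while Mki67 (52.7 against 466 CPM, -3.14), the kinesin Kif11 (-3.29), Gas2l3 (-3.38), Col23a1 (-3.17), Adamts14 (-3.12) and Kntc1 (-3.00) were lower.

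The place of tumour cells beside the stem cells depended on the choice of identity genes. The median level of 19 HFSC identity genes was 147 CPM in Tbr HFSC and 17.4 CPM in Tbr EpdSC. It was 10.4 and 13.7 CPM in the high and low gates of HRas tumours, 6.75 and 20.6 CPM in HRas TbrKO and 39.2 and 30.4 CPM in TbrKO tumours. The percentiles rank the median log2 level of these genes against each gene's mean over the DS libraries, not the CPM median. That mean includes the stem cell libraries, so tumour percentiles depend on them too. Among random lists matched on expression this log2 median stood at percentiles 100 and 0.02 in the stem cells, 0.08 and 1.44 in HRas, 0 and 1.70 in HRas TbrKO and 74.2 and 31.7 in TbrKO tumours. For 15 EpdSC identity genes the tumour percentiles were 0 and 0 in HRas, 0.20 and 1.01 in HRas TbrKO and 99.3 and 96.2 in TbrKO tumours, against 99.8 and 99.2 in Tbr HFSC and EpdSC, so that list did not part the lineages here. The genes called in BK gave another order. The 910 HFSC-high genes of BK stood at percentiles 0 and 100 in the high and low gates of HRas, 0 and 100 in HRas TbrKO and 100 in both gates of TbrKO tumours, against 100 and 0 in Tbr HFSC and EpdSC. Their log2 medians against the mean of the DS libraries were -0.19 and 0.17, -0.56 and 0.10, and 0.54 and 0.45 in the tumours and 0.96 and -1.42 in the stem cells. The 895 EpdSC-high genes of BK stood at 100 in both gates of HRas and HRas TbrKO and at 0 in both gates of TbrKO tumours, against 0 and 100 in Tbr HFSC and EpdSC, with log2 medians of -0.30 to 0.21 in the tumours. Fibroblast markers, of which 4 of 7 were higher in HFSC than in EpdSC of BK, were lower in the high than in the low gates for 6 of 8, with a median of -2.47 (adjusted p = 0.251 with an estimated correlation), so RNA of another cell type moved with the gate contrast of the HFSC-high genes. Single genes departed from the lists, as Cd34 stood at 37.7 to 61.6 CPM in the tumours against 12.0 CPM in EpdSC of BK, Sox9 at 54.2 to 273 CPM and Ly6a at 432 to 864 CPM.

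Open chromatin was compared between HFSC, EpdSC, wound cells and SCC stem cells by peak overlap. Of 20050 HFSC peaks that EpdSC shared, 90.1% were overlapped by a wound peak and 77.9% by an SCC peak. Of 35382 peaks seen in HFSC and not in EpdSC, 36.7% (Wilson 95% interval 36.2% to 37.2%) overlapped a wound peak and 28.8% (28.4% to 29.3%) an SCC peak. Of 5552 peaks seen in EpdSC and not in HFSC, 56.1% (54.8% to 57.4%) overlapped a wound peak and 34.9% (33.6% to 36.1%) an SCC peak, against 2.11% to 3.48% on average after shifts. Peaks in neither unwounded list made up 39.4% of wound and 47.2% of SCC peaks, and 43.9% of the former overlapped an SCC peak. The lists held 55435 HFSC, 25742 EpdSC, 56865 wound and 54201 SCC peaks from 26825550, 13963471, 11140895 and 29579794 fragments, so peak numbers can move with depth, and with 1 pooled list per population no difference was tested.

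**Figure D4:**
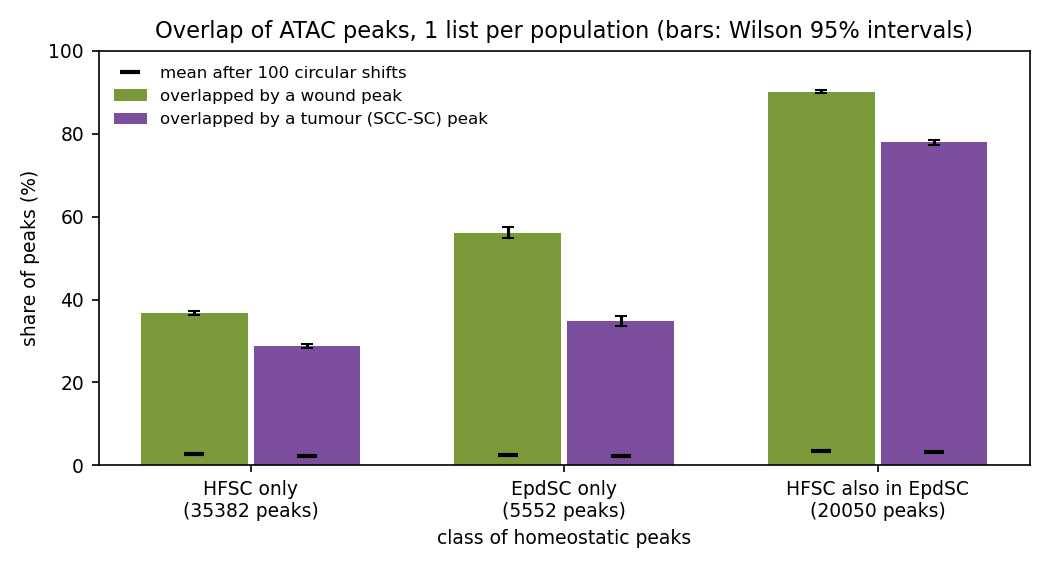
Percent of HFSC-only (35382), EpdSC-only (5552) and shared HFSC (20050) peaks overlapped by wound and by SCC peaks, with Wilson 95% intervals as error bars and the mean of 100 shifts as dashes. Shared peaks stood highest (90.1% and 77.9%), and wound peaks overlapped 36.7% of HFSC-only and 56.1% of EpdSC-only peaks.

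Around the HFSC identity genes HFSC had 201 peaks, EpdSC 48, wound cells 109 and SCC cells 103. Lhx2 (mm10 chromosome 2, 38339271 to 38369737) had 11 peaks in HFSC, 2 in EpdSC, 4 in wound and 1 in SCC cells. Postn (chromosome 3, 54359267 to 54391041) had 5, 1, 0 and 0, and Krt24 (chromosome 11, 99279959 to 99285262) 7, 0, 1 and 0. Cd34 (chromosome 1, 194938821 to 194961292) had 5, 2, 3 and 3, and Sox9 (chromosome 11, 112782210 to 112787757) 4, 1, 4 and 5. Around wound keratins and alarm proteins there were 27, 12, 47 and 38 peaks, of which 24 wound and 19 SCC peaks lay in neither unwounded list. Krt6a (chromosome 15, 101689928 to 101694305) had 6, 1, 9 and 9 peaks, S100a8 (chromosome 3, 90669071 to 90670034) 1, 0, 4 and 3, and Ly6a (chromosome 15, 74994877 to 74998031) 0, 0, 2 and 2. Of the ETS, STAT and NF-kB list, with 68, 42, 88 and 70 peaks, Elk3 (chromosome 10, 93247415 to 93311159) had 7, 1, 11 and 8, and 8 of its wound peaks lay in neither unwounded list. EpdSC identity genes had 69, 31, 79 and 53 peaks and AP-1 genes 64, 27, 44 and 52, with Fosb (chromosome 7, 19302696 to 19310118) at 9, 3, 5 and 7.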

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

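The tests below for RNA that reached both wounded gates and for endothelial cells were chosen only after the results were seen, and the other tests had their outcomes written down before they were computed. The results in this part stand out because the wound responses of the HFSC lineage and of EpdSC differed, by an edgeR test of the difference of the responses itself (n = 2 libraries in each of 4 groups). It called 2339 genes at an adjusted p under 0.05, and a negative difference means a lower response in the HFSC lineage. Leaving out most single libraries moved the count, and without wounded EpdSC B its balance turned, as given above.

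Of 20 HFSC identity genes 11 had a lower response in the HFSC lineage than in EpdSC and 1 a higher one, and the list call was lost with an estimated correlation (adjusted p = 0.313). The difference was -8.37 ± 0.73 for Cd34 (edgeR adjusted p = 0.000769), -4.52 ± 0.36 for Lhx2, -2.21 ± 0.37 for Sox9 and -2.19 for Nfatc1. It was -2.59 for Tcf7l1, -4.27 for Tbx1, -4.86 for Fgf18 and -3.82 for Lgr5. The signalling genes Bmp6 (-5.96), Wif1 (-7.73) and Dkk3 (-4.10) had positive log2 fold changes in wounded EpdSC and fell in the wounded HFSC lineage, while Npnt (1.53) fell further in EpdSC. Wif1 stood at 0.0313 CPM in EpdSC, below the floor of 3 counts per library, so its value of 2.94 in wounded EpdSC started near 0. Among EpdSC identity genes, Ly6a (1.63 ± 0.40, edgeR adjusted p = 0.0346), Klf5 (2.42 ± 0.47), Gata3 (2.39) and Hes1 (2.09) had higher responses in the HFSC lineage, and Sox7 (-1.18) and Irx4 (-3.21) lower ones. Unwounded cells were sorted on CD34 and Sca1, which Ly6a encodes, and wounded cells on YFP. The differences of Cd34 and Ly6a were therefore partly set by the gates.

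Outside the identity lists, the BMP receptor Bmpr1b (5.75 ± 0.89), the deiodinase Dio2 (5.71), the transcription factor Sox6 (5.25 ± 0.72) and Skint7 (5.16) had large higher responses in the HFSC lineage. Tmprss11g (7.40) and Prrg3 (6.35) were each at 0 in a group, so that their fitted values are no bound. Large negative differences were those of Crabp1 (-13.01 ± 1.25), Col6a2 (-12.57 ± 0.67), Col1a2 (-12.29 ± 0.65) and the leukocyte gene Wdfy4 (-11.74). Fgr (-12.32) and Cck (-11.64) were at 0 in a group as well.

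Beside these genes stood a pattern of RNA typical of leukocytes and fibroblasts in wounded EpdSC, whose share among the called genes was not counted. Of 18 further marker genes, 77.8% stood at 5 CPM or more in both wounded EpdSC libraries and over 4-fold above the wounded HFSC lineage, 10 of 10 leukocyte and 4 of 5 fibroblast genes, so cells of those types in the gate are a candidate explanation, although a lineage-negative gate should remove leukocytes. Their most abundant genes were H2-Ab1 (1720 against 18.3 CPM in the wounded HFSC lineage), H2-Eb1 (1270 against 10.9 CPM) and Laptm5 (320 against 3.14 CPM), but Col6a1, at 65.5 CPM, stood at 159 CPM in unwounded HFSC, and C1qb and Col6a2 had been seen as large changes when the marker set was written. RNA that reached both wounded gates alike was argued against by the known markers, with a median log2 fold change of 0.33 (quartiles -2.56 to 1.64) in the wounded HFSC lineage and 6.77 (4.76 to 7.88) in EpdSC, a test whose spread condition was set after its value was seen. Endothelial cells cannot be told apart from none, since 0% of 3 further endothelial genes passed, Cav1 being at 243 to 552 CPM in every CL group and Esam and Cldn5 at 1.85 and 0.296 CPM in wounded EpdSC.

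A further pattern was the fall of the BK genes of HFSC in the wounded HFSC lineage. A trend with gene length was argued against as its whole cause, since the median was -2.09 with the trend removed, between -2.13 and -2.02 over the 4 pairs of libraries, a range that was added to the test after its value was seen. Upper follicle cells brought in by the YFP gate could not be excluded. As a set 9 of their genes did not rise in the wounded HFSC lineage, with a median of -1.49 (quartiles -2.49 to -0.12). Lrig1 was at -2.97 and Gata6 at -4.37 although Klk10 was at 3.42. In wounded EpdSC, however, the set had a median of -0.02, and Lrig1 (-2.18) and Gata6 (-3.00) fell there too. Such cells may thus lose these markers in a wound, which the test cannot tell from their absence. A loss of follicle identity on wounding may remain as a hypothesis, untested against such cells and against the change of gate, from CD34 to YFP, that went with the wound.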

How the results depend on the processing

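Alternatives chosen only after seeing the data were those named as such above and gene families without the length trend. The test on other splits of the tumour libraries was also chosen after the result was seen, and the cause of each change below was not tested unless stated. Of 4346 values of named genes under alternatives that kept all libraries, 4177 kept their direction and their side of the threshold, 169 kept the direction alone and 0 reversed, and of 4345 values with a library or pair left out these were 3616, 729 and 0. The named genes counted had all passed in the main fit, mostly chosen for large folds or small adjusted p, so reversals were unlikely. A library had at least 14216472 counts and a group 1 or 2 libraries. In simulated counts with 200 changed genes edgeR recovered 0% of 2-fold changes in every CL and BK comparison, although smaller changes were called in CL. Peaks at named genes had no alternative, list counts were compared with DESeq2 only where edgeR called 0, identity levels in tumours changed with the choice of genes, and ATAC motifs was not run for want of the genome sequence.

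DESeq2 size factors moved the tumour gate count from 476 to 256. Without the filter on low counts, where more genes were tested, edgeR called 4303 between the wounded groups, 2131 in the BK wound comparison and 777 between tumour gates. The DESeq2 Wald test called 5336, 3410 and 1692 in these and 3909 for the difference of responses. Fits of only the 4 libraries compared called 2502 between HFSC and EpdSC and 1037 between the wounded groups. With the length trend removed the BK wound comparison called 2401. Among genes seen in other unwounded stem cell libraries, a smaller set by construction, 1534 were called between the wounded groups and 1351 for the difference of responses. Without a genotype block edgeR called 0 genes between tumour gates, where 1119 had an unadjusted p under 0.05. Leaving out both wounded EpdSC libraries gave 2323 genes between HFSC and EpdSC and 8154 in the wounded HFSC lineage.

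With each library left out in turn, the counts ranged from 505 to 2198 for HFSC against EpdSC, 4064 to 7915 for the wounded HFSC lineage, 5735 to 9382 for wounded EpdSC, 541 to 7460 between the wounded groups and 789 to 6499 for the difference of responses. They ranged from 1260 to 6486 and 6635 to 6848 in the BK comparisons and from 0 to 2908 between tumour gates. There edgeR called 0 without the HRas or the HRas TbrKO pair, with 1685 and 1684 genes at an unadjusted p under 0.05, and 2908 without the TbrKO pair. The median of the BK genes of HFSC in the wounded HFSC lineage ranged from -2.18 to -1.98 without single libraries, and the camera call was lost with each wounded library left out. The difference of medians between wounded groups, -0.21, ranged from -0.25 to -0.04, and was -0.06 for genes called in BK and CL, -0.10 with the length trend removed, -0.19 without markers of other cell types and -0.13 without genes over 2-fold lower in integrin alpha 6 high tumour cells.

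With the replicate letter as a block, edgeR called 1470, 6451, 8487, 2083 and 1966 genes in the 5 CL comparisons, and 2478 against 2264 without it among the 4 unwounded BK libraries, all within 1.5 times. The samples share only a letter or number, and the deviations of samples with the same letter correlated between -0.182 and 0.455 in CL and at -0.218 in BK.

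Of the 6 tumour libraries 10 splits into groups of 3 are possible, too few for a share under 0.05. The real split called 476 genes and the highest other 0, so 1 split of 10 called as many, with 15 to 1158 genes at an unadjusted p under 0.05 in the other edgeR fits. With the genotype block, splits that put both gates of a genotype on 1 side rest on 1 pair of libraries and repeat each other. Only splits with 1 library of each genotype per side are like the real one, and the others of that kind had 15 to 843 such genes. All splits had first been fitted without the genotype block, where each, the real one included, called 0 (4 to 3194 at an unadjusted p under 0.05).

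Peak shares moved with most alternatives for overlap, given here for a -log10 q of at least 5, for equal numbers of top peaks and for a reciprocal overlap of 50%. Wound peaks overlapped 39.1%, 23.4% and 28.9% of HFSC-only, 60.2%, 34.3% and 42.2% of EpdSC-only and 91.0%, 76.9% and 80.4% of shared HFSC peaks. SCC peaks overlapped 31.0%, 18.3% and 22.2%, 37.4%, 23.4% and 32.6%, and 79.5%, 67.0% and 67.6% of these. Of wound peaks in neither unwounded list 46.8%, 45.0% and 33.4% overlapped an SCC peak, and of such SCC peaks 42.2%, 33.0% and 31.1% a wound peak. Top peaks and reciprocal overlap put 31.8% and 51.3% of wound and 43.8% and 59.3% of SCC peaks in neither list.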

Other observations

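The gene families in this part, and the tests of dilution by other cells and of handling, were chosen only after the results were seen. No family was tested as a whole, so these are counts of single genes. Of 12 small proline-rich proteins, which build the cornified envelope, 11 were higher in each wound response of CL, with medians of 9.32 in the HFSC lineage and 9.99 in EpdSC, while 6 of 13 were lower in tumour cells of high integrin alpha 6. Of 93 genes of ribosomal proteins 37 were higher and 3 lower in the wounded HFSC lineage (median 0.67) and 53 and 6 in wounded EpdSC (median 0.97). With the trend with gene length removed these were 29 and 7 (0.39) and 24 and 13 (0.25), so the shift depended in part on that trend, which had a Spearman rho of -0.127 and -0.369 in these comparisons. Of 28 integrin genes 14 rose and 6 fell in wounded EpdSC, beside the leukocyte and fibroblast RNA of those libraries, and 10 were lower and 1 higher in the wounded HFSC lineage than in wounded EpdSC. Wnt ligands were lower in HFSC than in EpdSC for 7 of 17 with 1 higher, and 8 fell and 2 rose in wounded EpdSC. Of 11 Skint genes, a family of epidermal immunoglobulin-like proteins, 5 fell and 1 rose in wounded EpdSC.

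Sex-linked RNA, scaled over all 21 RNA libraries, differed although every sample was labelled female. The Y-linked gene Eif2s3y stood at 56.4 CPM in HFSC and 64.7 CPM in EpdSC of BK and at 0 in wounded EpdSC of BK, where Xist stood at 2140 CPM against 0.661 and 3.13 CPM in the unwounded groups. In CL, Xist stood at 2040 CPM in HFSC and 2960 CPM in EpdSC, and at 447 and 55.6 CPM in the wounded HFSC lineage and wounded EpdSC. Eif2s3y stood at 0.0385 CPM in HFSC of CL and at 0 in the other CL groups. The Xist difference in CL thus came almost without Y-linked RNA, unlike that in BK. In DS, Eif2s3y ranged from 21.4 to 101 CPM and Xist from 43.0 to 1670 CPM.

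AP-1 and dissociation stress genes were lower in both wounded CL groups. The 17 genes of both lists had medians of -3.96 in the wounded HFSC lineage and -3.66 in wounded EpdSC. A trend with gene length was argued against as the whole cause, since the medians were -4.25 and -4.41 with it removed (-4.61 to -4.07 and -4.54 to -4.28 over pairs of libraries, a range added after the value was seen), and so was dilution by cells of other types, since basal epithelium genes had a median of -0.61 (quartiles -1.71 to 0.04) in wounded EpdSC. Handling that differed between wounded and unwounded CL libraries cannot be told apart from an effect of the wound, as the lists had a median of -1.05 (quartiles -1.97 to -0.38) in the wounded BK library, between the values set for either outcome, and 1 wounded library could decide neither. Faster or gentler preparation of wounded cells may therefore account for the fall, as may lower AP-1 expression in the wound, and the heat shock genes Hspa1a, Hspa1b and Dnajb1 had medians of -0.62, 0.95 and -1.21 in the wounded HFSC lineage, wounded EpdSC and wounded BK cells.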
